A study of Tetrahymena thermophila with 9 samples.

How the data were processed

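The series holds 9 samples of Tetrahymena thermophila grown vegetatively in a rich liquid medium: 2 chromatin immunoprecipitates of FZZ-tagged Ibd2 with 2 inputs, and 5 poly(A) RNA libraries, 2 from wild type and 3 from Ibd1 knockout cells. Groups were taken from the sample titles. Per the labels, chromatin was isolated from sonicated nuclei on an anti-FLAG gel, and RNA libraries were made with a directional kit after poly(A) selection. The protocol text names Ibd1 as the tagged protein where titles and genotypes name Ibd2, and Ibd2 is used here.

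BWA, SAMtools, MACS2, STAR, DESeq2 and FastQC are named in the submitters' processing notes, without the step each served. The genome build, the annotation, the read counter, the peak calling threshold and the rule for the reproducible set are not given in the sources used here. The peak list holds 13847 peaks in 3 sets, named by the authors as replicate 1, replicate 2 and reproducible. It gives each peak's scaffold, start, end and width, an annotation class, a gene and a distance to the transcription start, per the file headers. Peaks were called separately for both replicates, judging by their names, and no height, enrichment or p-value per peak is listed. From the values, the promoter class covers peaks from −998 to 100 bp around the transcription start, with 0 peaks of another class inside these bounds, and a distance of 0 marks a peak that covers the start.

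The RNA table holds normalised gene counts, a non-negative signal that the authors made by dividing reads by scaling factors, judging by the deposited values. Their mean per gene equals the mean listed in the deposited comparison. The authors' deposited comparison gives a log2 fold change with its standard error, and a p-value and adjusted p-value, per the file headers. The fold change divided by its standard error gives the listed p within 10% for only 18.1% of the genes, so the deposited fold changes look shrunken. Low values lie near whole multiples of 1 step per library (1.401 and 1.503 in the wild type columns, 0.5313, 0.7464 and 1.206 in knockouts B, C and C2), but not nearly all of them do. Of the values up to 20 steps, 91.0% and 88.8% in the wild type columns and 91.1%, 95.5% and 93.1% in knockouts B, C and C2 lay within 10% of a step from a whole multiple, where chance gives 20%. Up to 5 steps the shares were 95.4% and 91.5% in the wild type columns and 97.1%, 98.6% and 96.9% in knockouts B, C and C2. A count model needed 95% in every library, which wild type column 2 missed at either reach, and was not run. Library sums divided by the steps gave the estimated depths, which are approximate. The sums of normalised reads were 22083308 and 25297003 in the wild type columns and 10904387, 12691452 and 16964420 in knockouts B, C and C2, which is why scaling to equal totals moves the balance of calls.

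The 2 wild type columns carry no strain, so they were assigned to the wild type group only. The knockout columns were matched by their letters. One knockout column, C, ends in another index number than its label does. The labels place all 5 RNA libraries on 1 plate strip, and the wild type pair is numbered apart from the knockouts, so any difference in handling between these would follow the groups. P-values measure the spread between these libraries.

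The main test was limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, on log2(normalised value + 1), for genes with a mean of at least 10 over the 5 libraries, with Benjamini-Hochberg adjustment at 0.05. It was tested on simulated data for this comparison with 18423 genes and 50 changed genes per fold size. It recovered 4% of 2-fold, 52% of 4-fold, 96% of 16-fold and 100% of 64-fold changes, with 8 false calls among 134. Far fewer genes changed in the simulation than were called in the data, and each simulated gene varied on its own. The recovery and false calls of the real comparison may therefore differ. Alternatives fixed before the data were examined were pseudocounts of 0.5 and 8, no filter, a minimum mean of 50, TMM factors computed from the values, quantile normalisation, no trend, both CU428 knockouts averaged, a 2-fold minimum, a threshold of 0.01, and leaving out each library in turn. Equal totals, the choice of abundant genes in one wild type column, the sorting of deciles and all peak alternatives were added after the data were seen. Deciles of RNA level were made from the mean of the group means on the log2 scale, and as alternatives from the wild type or the knockout level. Calls by decile used the mean over the 5 libraries. The top wild type decile was also read with the level from one wild type column and the fold change from the other, averaged over both choices.

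Peaks were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. Overlap meant at least 1 bp, or 50% of both peaks as an alternative. Chance overlap came from 200 circular shifts along each scaffold. Widths were compared on the log scale by permutation tests and classes by Fisher's exact test with adjustment over 9 comparisons. Within width classes, odds ratios were pooled by the Mantel-Haenszel method with Robins-Breslow-Greenland intervals. Locus tags of all 6645 genes in the peak list matched the reference table of RefSeq genes (assembly JCVI-TTA1-2.2), which served for the number and order of genes, and none of its coordinates was used. That table gives locus tags in place of gene names, so peaks carry locus tags only.

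Several planned steps were not possible. The rule for named genes was IBD1, other bromodomain genes, and the genes with the largest fold changes with a known product. Since the RNA table has gene numbers alone, only the 2 genes with the largest change in each direction were named, among those past the threshold whose groups do not overlap. The rule for peaks was the largest fold enrichment, and width was used in its place. Gene lists, strain comparisons, peak shares against random placement in the genome, and all joins of RNA with peaks were left out for the same reasons.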

Results

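The series examined 2 bromodomain proteins, Ibd1 and Ibd2, in vegetatively growing Tetrahymena thermophila, a ciliate that keeps a germline micronucleus and a transcribed somatic macronucleus in the same cell. Bromodomains bind acetylated lysines, chiefly on histones. The series title places the work around Ibd2 and Hv1, the Tetrahymena form of the histone variant H2A.Z. Of the 9 samples, 2 were chromatin immunoprecipitates of Ibd2 carrying the FZZ affinity tag, 2 were the matching input chromatin, 2 were wild type poly(A) RNA libraries, and 3 were poly(A) RNA libraries of Ibd1 knockout cells. The wild type pair came from the strains B2086 and CU428. Knockout library B was made in B2086, and knockout libraries C and C2 were made in CU428. The labels call the samples biological duplicates and triplicates and say no more about the cultures.

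The first comparison asked where Ibd2 lay on the genome and whether both immunoprecipitates found the same places. Peaks of the reproducible Ibd2 set were annotated to the 5′ ends and exons of genes, and hardly any to sequence far from a gene. The deposited reproducible set held 1900 peaks, of which 59.3% were annotated to a promoter (95% Wilson interval 57.1 to 61.5%) and 39.8% to an exon (37.6 to 42.0%). Only 14 peaks, 0.737%, were distal intergenic, and 1 was intronic. In 46.5% of the reproducible peaks (44.3 to 48.8%) the peak covered the annotated transcription start of its gene. Only 1.79% lay wholly upstream of the start, so the promoter class here is mostly not upstream sequence alone. The 1900 peaks belonged to 1750 genes, 6.48% of the 26996 genes in the reference table. Of these genes, 1610 carried 1 reproducible peak, 130 carried 2 and 10 carried 3. Peaks had a median width of 665.5 bp (interquartile range 506.75 to 946.25 bp) and together covered 1.49 Mb. These intervals cover counting error only, and neighbouring peaks are not independent. Random placement in the genome was not tested, so the shares do not show a preference for any class. Among all replicate 1 peaks, 5.51% were distal intergenic. The shares of the reproducible set rest on its deposited bounds, which equalled a replicate 1 peak for 1585 peaks and a replicate 2 peak for 26. The 1946 replicate 2 peaks that overlapped the set were narrower, with a median width of 503 bp. Of these, 48.6% were annotated to a promoter and 50.4% to an exon, and 34.9% covered a start.

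The widest reproducible peaks all sat over transcription starts, which a wide peak does more easily by its length alone. The widest was a 4618 bp peak at the start of TTHERM_000649479, on scaffold scf_8254644 from 342808 to 347425. It had no replicate 2 peak assigned to the same gene. All 1900 reproducible peaks overlapped a replicate 2 peak, so the one it overlapped was assigned to another gene. Next came a 4160 bp peak at TTHERM_000310158, on scf_8254551 from 459329 to 463488. A 3446 bp peak covered the start of TTHERM_01091280, on scf_8254241 from 7246 to 10691. The peaks at TTHERM_00334470 and TTHERM_00938820 were 3006 bp and 2759 bp wide. The peak at TTHERM_00301890, on scf_8254379 from 694002 to 696722, was 2721 bp wide and carried number 1 in the reproducible set. All these widths exceeded that of the widest replicate 2 peak, 2219 bp, so no single replicate 2 peak had such a width. Genes with 3 reproducible peaks included TTHERM_00147510, whose peaks lay between 19087 and 21967 on scf_8254545, and TTHERM_00466120, whose peaks lay between 81215 and 85852 on scf_8254371. The list gives neither heights nor enrichments, so these genes were taken by width or number of peaks after the values were seen. Coordinates are those of the deposited list, for which the build is not given in the sources used here.

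**Figure D1:**
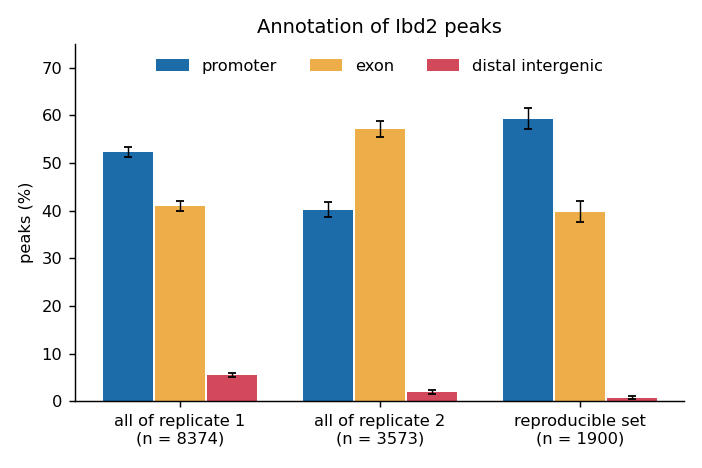
Share of Ibd2 peaks (%, vertical axis) annotated to promoters, exons and distal intergenic sequence, for all 8374 peaks of replicate 1, all 3573 peaks of replicate 2 and the 1900 peaks of the reproducible set. Error bars are 95% Wilson intervals, and the promoter share is 52.4%, 40.2% and 59.3% in that order.

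The 2 immunoprecipitates gave peak lists of different length that were largely nested. Replicate 1 had 8374 peaks in 6496 genes and replicate 2 had 3573 peaks in 3001 genes. Of the replicate 2 peaks, 93.6% overlapped a replicate 1 peak by at least 1 bp, against 11.4% on average when the replicate 2 peaks were shifted along their scaffolds (at most 457 peaks in 200 shifts, 3344 observed). With an overlap of at least 50% of both peaks the share was 76.3%. In the other direction 38.5% of the replicate 1 peaks overlapped a replicate 2 peak. Both lists named 2852 genes in common, where independent lists of these lengths would share 722. Each of the 1900 reproducible peaks had the outer bounds of the replicate peaks it overlapped. The 229 replicate 2 peaks that overlapped no replicate 1 peak were narrow, with a median width of 299 bp, and 82.1% were in exons and 14.8% in promoters. They were not tested against the other peaks, and among replicate 1 peaks the promoter share was also lower at small width.

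Peaks of replicate 1 that entered the reproducible set were wider and lay at starts more often than the others. Their median width was 661 bp, against 478 bp for peaks that overlapped replicate 2 without entering the set and 410 bp for peaks found in replicate 1 alone. Each of the 3 differences had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. The classes were made by overlap, which a wider peak meets more easily by its length. Part of the difference was thus fixed in advance, and peaks are not independent. Start coverage was 46.4% in the reproducible set, 29.6% in the overlapping remainder and 31.4% in replicate 1 alone. The difference between the first and the last had an odds ratio of 1.89 (Fisher's exact test, adjusted p = 2.75e-30 over 9 comparisons). Between the overlapping remainder and replicate 1 alone, start coverage did not pass the threshold (adjusted p = 2.05e-01). Distal intergenic peaks made up 0.736% of the first class and 7.88% of replicate 1 alone (odds ratio 0.0867, adjusted p = 8.71e-39).

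The excess of start coverage was not seen among peaks of like width. When the replicate 1 peaks of these sets were divided by width into 5 classes of equal size, the common Mantel-Haenszel odds ratio for start coverage between the reproducible set and replicate 1 alone was 1.07 (95% interval 0.945 to 1.21). Among peaks of 755 to 4618 bp, 63.5% of the reproducible and 61.5% of the replicate 1 alone peaks covered a start. Among peaks of 422 to 543 bp the shares were 30.2% and 28.4%. For promoter annotation the direction turned on the division by width. Undivided, 59.1% of the reproducible and 52.01% of the replicate 1 alone peaks were in promoters (odds ratio 1.33, Fisher's exact test, adjusted p = 1.70e-07 over 9 comparisons), and the common odds ratio within width classes was 0.792 (0.70035 to 0.895). In the width range of 422 to 543 bp the reproducible peaks were annotated to promoters less often, at 42.6% against 53.9% (Fisher's exact test, adjusted p = 5.43e-04 over 10 tests, the only 1 of them past the threshold). This division by width was chosen after the data were seen, and distal intergenic peaks were not compared within it.

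**Figure D2:**
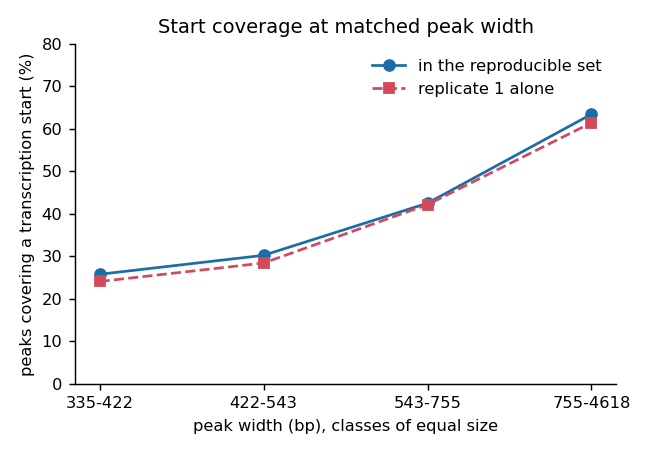
Share of replicate 1 peaks covering an annotated transcription start (%, vertical axis) against peak width (bp, in 5 classes of equal size), for peaks in the reproducible set (circles, solid line) and peaks found in replicate 1 alone (squares, dashed line). The narrowest class is left out because it holds 1 reproducible peak, and in the widest the shares are 63.5% and 61.5%.

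Genes with a reproducible Ibd2 peak were neighbours more often than chance. In the gene order of the reference table, 203 pairs of adjacent genes both carried a reproducible peak, against 121 ± 10.1 (mean ± SD) in 100000 permutations of the genes, whose highest value was 163. The two-sided permutation p was 1e-05, the smallest the permutations can give, and the longest run was 6 genes. In 173 of the 203 pairs the nearest peaks of both genes were at least 1000 bp apart. Counting promoter peaks alone, 81 pairs were seen and 49.1 expected. No single scaffold stood out. Across 248 scaffolds with at least 20 genes, the share of genes with a reproducible peak ran from 0 to 19.4%, and 0 passed a two-sided exact binomial test with Benjamini-Hochberg adjustment, while 16 had an unadjusted p under 0.05.

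The second comparison asked how poly(A) RNA differed between Ibd1 knockout and wild type cells. The deposited table covers 23859 numbered genes. It pairs those numbers with neither locus tags nor names, so the IBD1 transcript was not looked up, no gene groups were formed, and the RNA values were not joined to the Ibd2 peaks. Most low values in each library were close to multiples of 1 step, which put the depth at about 15800000 and 16800000 reads in the 2 wild type columns and about 20500000, 17000000 and 14100000 reads in knockout libraries B, C and C2. The wild type columns name no strain and are called column 1 and column 2.

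Many genes changed in the knockout, in both directions and by large factors. Of 18778 genes tested, 1836 were higher and 1803 were lower in the knockout, together 19.4% (limma on log2 of the normalised value plus 1, Benjamini-Hochberg adjusted p under 0.05, wild type n = 2 and knockout n = 3). All of these differed at least 2-fold. At least 4-fold changes numbered 927 higher and 1166 lower, and at least 16-fold changes 198 higher and 266 lower. All 3 knockout values lay on one side of both wild type values for 54.6% of the tested genes, where chance gives 20%. In all, 12 genes stood below 5 normalised reads in both wild type columns and at 100 or more in every knockout library, and 23 genes showed the opposite.

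Some single genes went from near silence to high abundance or the reverse. Gene g8054 rose from 30.93 and 3.25 normalised reads in wild type to 12146.27, 15876.31 and 9244.04 in knockouts B, C and C2 (log2 fold change 10.02, SE 0.78, limma adjusted p = 2.40e-03). Gene g12861 was listed at 0 in both wild type columns and at 1339.21, 2138.06 and 5233.07 in the knockouts (limma adjusted p = 6.41e-04). Gene g21523 fell from 4536.68 and 7754.06 to 1.06, 0 and 3.63 (log2 fold change −11.45, SE 0.67, limma adjusted p = 8.74e-04). Gene g11086 fell from 4216.75 and 4758.68 to 0.53, 0.74 and 38.52 (log2 fold change −9.89, SE 1.32, limma adjusted p = 6.85e-03). Both genes that fell missed the threshold when either wild type column was left out, which leaves 1 library in that group, while their log2 fold changes stayed at −11.84 and −11.06 for g21523 and at −9.98 and −9.80 for g11086. These calls had limma adjusted p between 0.0510 and 0.1002 and ranges over all alternatives of 1.10e-04 to 0.0617 for g21523 and 1.92e-04 to 0.1002 for g11086. All fold changes are on the log2(value + 1) scale, and their size is loosely fixed. That of g8054 was 11.48 without wild type column 1 and 8.57 without column 2. With knockout values near 0 the pseudocount sets much of the fall, which was −11.97 with a pseudocount of 0.5 and −9.30 with 8 for g21523, and −10.25 and −8.21 for g11086.

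The number of calls rested on few libraries. Without wild type column 1 there were 15 higher and 8 lower genes, and without column 2 there were 11 and 7. The counts were 738 and 786 without knockout B, 523 and 558 without knockout C, and 3068 and 3703 without knockout C2. The balance of directions rested on the scaling. With every library scaled to the same total, an alternative added after the data were seen, 4855 genes were higher and 904 lower, because the median of all tested genes then moved to 0.81 on the log2 scale from −0.01 under the deposited scaling.

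Under the deposited scaling, genes with the highest mean level over both groups were lower in the knockout relative to the rest. In the top decile of RNA level, taken as the mean of both groups, the median log2 fold change was −0.92 (SD 0.23 between the medians of the 3 knockout libraries, n = 3), a difference of −0.98 from that of the other genes. The medians were −1.02 in knockout B, −0.77 in C and −0.56 in C2. The upper end of the RNA levels was also lower, with the 99th percentile of log2 values at 14.37 and 14.62 in the wild type columns and at 12.59, 12.86 and 13.34 in knockouts B, C and C2. Whether these genes were lower than in wild type rests on the scaling, since the top decile lay at −0.090 with equal totals (with B and C at 0.095 and 0.13). With quantile normalisation of the tested genes it lay at −0.12. The median over all tested genes was 0.025 in a separate run, in which all listed genes were normalised. The fall relative to other genes thus appeared to shrink as well under quantile normalisation, which makes the libraries alike in spread. Its size and sign also rest on how the genes are sorted. Sorting by the wild type level, which by itself favours a fall of high genes and a rise of low genes, gave −1.42 in the highest and 1.24 in the lowest decile. Sorting by the knockout level gave −0.11 and −0.57, so the rise of the lowest genes turned with the sorting. With each knockout library sorted by and read in itself, the top decile lay at 0.11 in B, 0.24 in C and 0.04 in C2. Sorted by 1 knockout library and read in the other 2, the top decile lay at 0.02 for B, −0.05 for C and −0.72 for C2. With level and change taken from different wild type columns, the top wild type decile lay at −1.39.

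Calls followed the same lean at the top. Among the 1878 genes in the top decile of the mean over the 5 libraries, 454 were called lower and 96 higher, against 1349 and 1740 in all other deciles (limma calls, Fisher's exact test, odds ratio 6.10, p = 1.56e-67, across genes, which are not independent replicates). The other deciles of mean level did not all lean the same way. Lower calls also outnumbered higher calls in decile 9, with 216 against 166, and in the lowest decile, with 197 against 176.

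**Figure D3:**
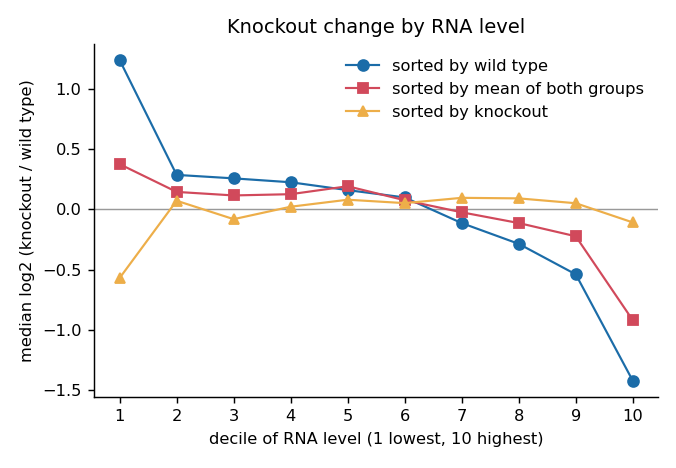
Median log2 ratio of knockout to wild type (vertical axis, means of 3 knockout and 2 wild type libraries) in deciles of RNA level (horizontal axis, 1 lowest, about 1878 genes each), with genes sorted by the wild type level (circles), by the mean of both groups (squares) or by the knockout level (triangles). The top decile lies at −1.42, −0.92 and −0.11 in that order, and the lowest at 1.24, 0.37 and −0.57.

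The 100 most abundant wild type genes held a smaller share of the RNA in each knockout library than in wild type, with a much smaller loss in C2 than in B and C. They made up 32.3% and 31.6% of the normalised reads in the 2 wild type columns, and 7.86%, 8.50% and 20.8% in knockouts B, C and C2. Of these 100 genes, 44 were called lower, 0 higher and 56 neither (limma). Their median log2 change from the wild type mean was −3.71 in knockout B, −3.56 in C and −1.04 in C2, where 48 of the 100 genes lay within 2-fold of wild type. These genes were chosen in the columns that serve as the baseline, which by itself lowers the change. With the genes chosen in one wild type column and the change read against the other, the medians were −3.68 and −3.54 in B, −3.36 and −3.47 in C, and −0.67 and −0.87 in C2. The 100 most abundant genes of the knockout, of which 46 were shared with the wild type list, gave a weaker mirror in their share but not in their medians. They made up 17.9% and 18.2% of the wild type columns and 19.5%, 22.9% and 29.8% of knockouts B, C and C2, with 8 called higher and 1 lower. Their median log2 change from the wild type mean was −1.50 in B, −0.84 in C and 0.24 in C2. Taking the 100 highest genes of each library itself, their share was 32.76% and 31.82% in the wild type columns, 21.5% in B, 24.3% in C and 31.77% in C2. By this measure C2 lay barely below the lower wild type column. A group of 10 of the 100 genes lay more than 16-fold below wild type in all 3 knockouts, from 7.84% and 4.80% of the wild type columns to 0.296%, 0.137% and 0.149% of knockouts B, C and C2.

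Knockout library C2 stood apart from the other 2 knockouts, although by the column letters it shares its strain with C. Across genes the Pearson correlation of log2 values was 0.956 between B and C, 0.857 between B and C2, 0.867 between C and C2, and 0.95004 between the wild type columns. Correlations between wild type and knockout libraries were between 0.733 and 0.790. Of the 1201 genes at least 4-fold lower in both B and C, 230 (19.2%) lay within 2-fold of the wild type mean in C2. Of the 742 genes at least 4-fold higher in B and C, 59 (7.95%) did. When genes were chosen in the same way without B or without C, between 0.339% and 1.24% of the chosen genes lay within 2-fold of wild type in the library left out.

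**Figure D4:**
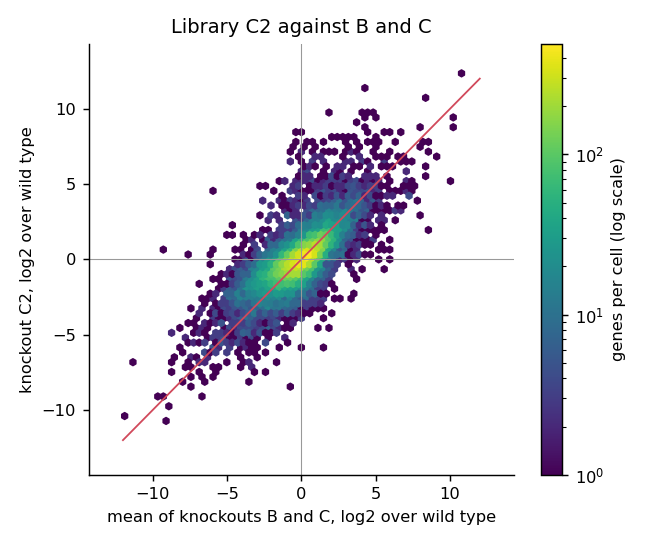
Log2 ratio to the wild type mean in knockout C2 (vertical axis) against the mean of knockouts B and C (horizontal axis) for the 18778 tested genes, with colour giving the number of genes per cell on a log scale and the red line marking equal values. Many genes that are low in B and C lie above the line, including the 230 of 1201 that are within 2-fold of wild type in C2.

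The authors' deposited table called more genes than limma, in the same directions. It lists 2624 genes higher and 2605 lower at an adjusted p under 0.05, with the adjusted p missing for 2799 genes. The limma calls shared 1836 higher and 1800 lower genes with the authors' deposited table, and 0 genes were called in opposite directions. A further 1593 genes were called in the authors' deposited table alone. Fold changes in the authors' deposited table correlated with those of limma across genes (Pearson 0.970, Spearman 0.988). Both rest on the same 5 libraries, so neither is independent of the other.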

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

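Equal totals, all alternatives for the top decile of mean level and all peak alternatives were chosen after the data were seen. No paired analysis was possible because the wild type columns do not name the strain or replicate they came from. The strain term, the CU428 comparison, the strain difference and its alternatives were not run for that reason. Count models on recovered reads were not run because fewer than 95% of values up to 20 steps were whole in 4 of 5 libraries. Up to 5 steps only wild type column 2 fell short, at 91.5%. Gene lists and joins with peaks were not run because the gene numbers have no names. Peak alternatives by q, enrichment, summit or gene window were not run because the list and the table lack these values. Leaving out 1 library gave 11 to 3068 higher and 7 to 3703 lower genes, the lowest where 1 wild type library was left, which is then assumed to vary like the knockouts. Averaging the CU428 knockouts gave 2874 lower genes. A threshold of 0.01 gave 323 higher and 293 lower genes, by its construction. Equal totals gave 4855 higher and 904 lower genes, a top wild type decile of −0.56 and a top decile of mean level of −0.090, through the shift of all genes. Quantile normalisation moved these medians to −0.75 (all listed genes normalised) and −0.12 (tested genes normalised), by making the libraries alike in spread. Sorting by the wild type or the knockout level moved the top decile from −0.92 to −1.42 or −0.11, by its construction. The promoter share was 72.1% in the reproducible peaks at or above their median width, 52.4% in all replicate 1 peaks and 40.2% in all replicate 2 peaks, and start coverage was 60.0%, 34.5% and 26.3%. Both shares rose with peak width. A wider peak takes in a start more easily by its length alone, and any cause beyond this was not tested. Overlap of 50% of both peaks gave 76.3% of replicate 2. Another 41 values of these results kept their direction and stayed within 1.5 times or their spread, among them the neighbour ratios, from 1.30 to 1.74. Choosing the 100 most abundant genes in one wild type column, another addition, left their medians below 0 in every knockout. Of the values for the 4 named genes, 60 kept direction and call, and 4 kept direction and about their size but missed the threshold, all without a wild type column. At 2 against 3 libraries a 2-fold change was seldom recovered in simulation, so genes not called are not shown to be unchanged.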

Other observations

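Of the 100 genes most abundant in wild type, 6 lay below 3% of their wild type mean in every knockout, a choice made after the values were seen that fixes their direction. All 6 were called lower by limma. Their levels lay between 220078 and 253511 normalised reads in wild type column 1 and between 146855 and 165832 in column 2. In the knockouts they lay between 1358 and 4865. Within each library the highest of the 6 was at most 1.59 times the lowest. Their share of all normalised reads was 6.39% and 3.72% in the wild type columns and 0.222%, 0.0787% and 0.102% in knockouts B, C and C2. The counting of near-identical copies is not given in the sources used here. The 230 genes at least 4-fold lower in B and C but within 2-fold of wild type in C2 had a higher wild type level than the other 971 genes lower in B and C. The medians were 2072 and 1408 normalised reads. The means of the log2 levels differed by 0.84 (permutation test of this difference over genes, p = 3e-04 with 100000 resamples).

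The number given to a reproducible peak was moderately related to its width. The Spearman correlation of number with width was −0.45 across peaks, which are not independent replicates. The 190 peaks with the lowest numbers had a median width of 1015.5 bp, 85.3% were in promoters and 78.4% covered a start. The 190 peaks with the highest numbers had a median width of 471.5 bp, 39.5% were in promoters and 25.8% covered a start. Since wider peaks take in a start more easily, these shares are not separate from width. The widest peak has number 254 and the peak with number 1 is 2721 bp wide, so width alone does not set the numbers, and the list does not say what they rank.

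All tests below were chosen after the result they bear on was seen. Genes of the top decile of mean level were lower in the knockout relative to other genes, by −0.98. Scaling by 1 factor per library cannot make this difference, since it moves all genes alike. Such scaling may set whether these genes were lower than in wild type at all, as the top decile lay at −0.090 with equal totals. A scale that varies with RNA level is not excluded by this. With quantile normalisation of the tested genes the top decile lay at −0.12, and the median over all tested genes was 0.025 in a separate run on all listed genes. That step would also remove a real change in spread, so it cannot decide. Without the 100 genes of highest mean level the difference was −0.94. A median over 1878 genes can hardly move when 100 of them are left out, so this is no separate test of a few very abundant genes. Sorting by the wild type level as the whole cause would put the top decile of knockout level well above 0. That decile lay at −0.11 for the mean of the 3 knockouts. It lay at 0.11, 0.24 and 0.04 in B, C and C2, each sorted by its own level. A part played by sorting therefore stays open. Loss of Ibd1, a difference in growth state of the cultures and any difference in library handling stay open, because each follows the groups and cannot be told apart here.

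Knockout library C2 differed from B and C in many genes that lay near wild type in C2. Wild type RNA mixed into C2 would raise all low genes alike, but 52.7% of the 1201 genes lay at 25% of wild type or less in C2, including 140 of the 254 with at least 10000 normalised reads in wild type, where 56 others lay at 50% or more. An earlier form of this test, a ratio of percentiles over genes at least 16-fold lower, had no finite value, since genes listed at 0 set the lower one. Strain background argues the other way, as C correlated better with B than with C2 of its own strain, by 0.0894. This rests on matching column C to its strain by its letter, as its index number differs from that of its label. A difference in scale alone was predicted to end the pattern under equal totals. There the same rule chose 545 genes in place of 1201, and 89 of them (16.3%) lay within 2-fold of wild type in C2 in place of 230. This cannot exclude a difference in scale, because equal totals moved the knockout libraries apart. Median log2 changes over all tested genes in B, C and C2 were 0.003, 0.028 and −0.001 under the deposited scaling. With equal totals they were 1.10, 0.91 and 0.47. A knockout culture in another growth state, or with another degree of replacement of the IBD1 copies in the macronucleus, is a candidate explanation that was not tested, since the IBD1 transcript was not looked up.

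Genes with consecutive numbers changed together, with a correlation of fold changes of 0.158 over 14811 pairs and 0.00057 for genes 50 places apart. Of the called genes, 439 consecutive pairs changed in the same direction, against 278 ± 15.3 (mean ± SD of 1000 permutations). A similarity not tied to the knockout is consistent with this, because the difference between the 2 wild type columns was as correlated between consecutive genes, at 0.165. Reads shared by overlapping gene models and regulation shared by neighbours were not tested apart, and the table does not say that the numbers follow the genome.

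Other splits of the 5 RNA libraries into 2 and 3 are too few to give a share under 0.05. Of 10 splits, 1 gave as many genes as the real one, the real one itself, with 3639 genes, and the highest of the others gave 12 genes.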
